A study of Homo sapiens with 12 samples.

How the data were processed

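RNA was measured on 12 single-colour Affymetrix expression arrays, 3 per group in 4 groups: RCC4 cells carrying an empty vector (Vec) or with VHL put back (VHL), each kept for 6 h in full DMEM or in cystine-deprived DMEM. Per the labels, total RNA was purified on silica columns, and biotin-labelled targets were made from it with the MessageAmp Premier kit. The deposited values are log2 expression values, one per probe set and array, for 22215 probe sets. Their unit was read from the values, which ran from about 3.26 to 14.79 with array medians between 7.12 and 7.18. Lower quartiles lay between 5.53 and 5.63 and upper quartiles between 9.15 and 9.18, as they would after a normalization between arrays. Whether and how the authors normalized is not stated in the sources used here. Values were used as deposited, with no further scaling and no filter on low values. Detection calls were not used here, so a fold against a group of dim values is limited by background signal. For arrays the number of replicates limits the precision.

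Of the 22215 probe sets, 19064 named 1 gene, 1043 named several genes and 2108 named none. Symbols were brought up to date through the RefSeq annotation of assembly GRCh38.p14 for 19052 probe sets. Each of 11963 genes was represented by its probe set with the highest mean over the 12 arrays, a choice that matters for the 4310 genes with more than 1 probe set. Probe sets naming several genes or none were tested apart and are reported only as counts. The annotation on the array predates current symbols, and COXFA4L2 is the current symbol of NDUFA4L2.

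One mean per group was fitted over all 12 arrays in limma 3.58.1 under R 4.3.3, with 8 residual degrees of freedom and 12.7 after moderation. The comparisons were deprived against control medium in Vec cells, the same in VHL cells, the difference between these responses (VHL minus Vec), and VHL against Vec cells in each medium. The first 2 comparisons share no arrays, nor do the last 2. P-values from limma's moderated test, all two-sided, were adjusted by the Benjamini-Hochberg method over the 11963 genes. A gene is called when its adjusted p is under 0.05. Errors after ± are standard errors of the fit unless given as SD, and intervals are 95% confidence intervals.

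A set of 24 gene lists was tested in each comparison with camera, limma's test of a list against the other genes, at a preset correlation of 0.01 between genes, with adjustment over the lists of that comparison. A list is called at an adjusted p under 0.05. Each test was repeated with the correlation estimated from the data, and the report gives which calls hold. The lists cover the ATF4 and amino acid response, aminoacyl-tRNA synthetases, NRF2 and glutathione, ferroptosis, necroptosis and death receptors, NF-kB targets, targets of the hypoxia-inducible factor HIF, glycolysis, endoplasmic reticulum chaperones, sterol synthesis, p53 targets, mitosis, DNA replication, immediate early genes, extracellular matrix, epithelial junctions, interferon response, heat shock, metallothioneins, ribosomal proteins, oxidative phosphorylation, and markers of proximal tubule, blood cells and endothelium. Counts of list members adjusted over the list alone used the same p-values with adjustment over that list's measured genes. A total of 21 genes stand in more than 1 list.

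Named genes followed a rule. It takes VHL, the 8 largest rises and 8 largest falls among called genes whose groups do not overlap, up to 4 called members of each list by smallest adjusted p (up to 2 members as values where none is called), and 10 genes tied to the question of the study. Of the 10 question genes, 6 have values, and the other 4, RIPK1, RIPK3, MLKL and CA9, are not analysed here. The measured members of the lists therefore do not include them. The groupings, comparisons, lists, naming rule and all alternatives but 1 were chosen before the data were examined.

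The overlap of the responses of both lines was tested with Fisher's exact test. Runs of 50 neighbouring genes along the chromosomes, ordered by the RefSeq annotation, were compared with 1000 shuffled gene orders. The labels number the replicates from 1 to 3 and call them biological replicates, without saying that cultures of equal number were handled together. Residuals of arrays sharing a number correlated between -0.268 and 0.235 over 18 pairs, with a median of 0.0526, and 5 of 12 arrays were closest to an array of their own number. Arrays of other numbers correlated between -0.350 and 0.291 over 36 pairs, with a median of -0.0179. The samples were therefore treated as unpaired. No batch or scan date is used here.

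The alternatives were quantile normalization, median centring of each array, leaving out genes with a mean at or under 6.47, the mean of a gene's probe sets, each probe set on its own, leaving out probe sets whose name ends in _x_at or _s_at (which may bind several transcripts), a variance trend with robust moderation, a fit of the compared groups only, array weights, replicate number as a block, leaving out each array in turn, a 1.5-fold minimum, and an adjusted p under 0.01. For the lists they also included the estimated correlation, the test fry, and leaving out genes shared between lists. The lower quartile of each array as a covariate was added after the data had been seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

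The workflow was tested on simulated data with 50 changed genes per size among 11963. A log2 change of 1 was recovered for 100% of genes in each comparison except the difference of responses, at 96%. A change of 0.5 was recovered for 78% in Vec deprivation, 80% in VHL deprivation and 70% in the difference, and one of 0.25 for 50%, 46% and 22%. False calls made up between 4.12% and 8.14% of calls. The simulated noise was independent between genes and few genes were changed, whereas in the data up to 47.2% of genes were called. These shares therefore need not hold for the real comparisons.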

Results

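The series profiled RCC4 cells, a line from a clear cell renal carcinoma that lacks functional VHL. VHL is the substrate-recognition part of a ubiquitin ligase that marks the alpha subunits of the hypoxia-inducible factors (HIF) for degradation. Cells with an empty vector (Vec) and cells with VHL put back (VHL) were each kept for 6 h in full DMEM or in DMEM without cystine, the oxidized form in which most cells take up cysteine. Each of the 4 groups had 3 arrays, which the labels call biological replicates without saying whether each came from a separate culture. Per the labels, both media held 10% serum, and dialysed serum is named only for the deprived medium. If the control medium held undialysed serum, the deprivation comparisons also include the change of serum. The title of the series concerns dependence on cystine and necrotic death in VHL-deficient cells, so the comparisons ask what cystine loss does to gene expression in each line and whether the responses differ.

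The array has 1 dim probe set for VHL itself, with group means of 5.85 ± 0.04 in Vec control, 5.99 ± 0.11 in Vec deprived, 5.99 ± 0.03 in VHL control and 5.94 ± 0.01 in VHL deprived cells (log2, SD, n = 3). VHL against Vec cells differed by 0.14 ± 0.05 in control medium (limma adjusted p = 0.0532) and by -0.05 ± 0.05 in deprived medium (limma adjusted p = 0.475). Deprivation was not called for this transcript in either line, with a log2 change of 0.14 in Vec cells (limma adjusted p = 0.213) and -0.05 in VHL cells (limma adjusted p = 0.583). The position of this probe set in the transcript is not known, so its level cannot check whether VHL was put back.

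In Vec cells, 6 h without cystine raised 26 of 36 measured genes of the ATF4 and amino acid response (camera adjusted p = 1.14e-44). CHAC1, an enzyme that degrades glutathione, rose 6.42-fold (log2 2.68 ± 0.10, limma adjusted p = 4.15e-09, n = 3 per group). CTH, which makes cysteine from cystathionine, rose by 2.14 ± 0.09 on the log2 scale, and SLC7A11, the transport subunit of the cystine-glutamate exchanger, rose 2.64-fold (1.40 ± 0.08). ASNS, which makes asparagine, rose by 1.48 ± 0.05. Among heat shock genes 9 of 14 fell (camera adjusted p = 1.60e-14), and among DNA replication genes 5 of 23 (6.53e-08).

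A total of 500 of 11963 genes were called in Vec cells, 253 higher and 247 lower, or 4.18%, with a median size of 0.29 on the log2 scale. Changes of at least 1.5-fold were mostly rises, 45 against 2 falls, and all 10 changes of at least 2-fold were rises. The other largest rises were INHBE, a secreted inhibin subunit, at 1.71, PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, at 1.31, KLF4, a transcription factor, at 1.30, and DDIT4, an inhibitor of mTORC1 signalling, at 1.25. The largest falls were smaller. CAMTA1, a calmodulin-binding transcription activator, changed by -0.65, DIXDC1, a protein of Wnt signalling, by -0.61, CHORDC1, a partner of HSP90, by -0.58, RHOB, a small GTPase, by -0.58, BRINP1 by -0.57 and ZCCHC2 by -0.56. VAV3 changed by -0.58 and CAVIN2, a coat protein of caveolae, by -0.56. Without Vec control replicate 1 or 2 or Vec deprived replicate 1, VAV3 was no longer called (adjusted p between 0.0744 and 0.0805), and CAVIN2 was lost without any 1 of 5 arrays, all but Vec control replicate 3 (0.0976 to 0.179). The count of called genes dropped to between 253 and 303 without any 1 of the 6 arrays, and to 233 without probe sets ending in _x_at or _s_at.

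Of the 36 measured genes of the ATF4 and amino acid response, which ATF4 induces when amino acids run short, 26 rose and 1 fell in Vec cells (27 and 1 adjusted over the list alone), with a median of 0.65 and a camera adjusted p of 1.14e-44. Among aminoacyl-tRNA synthetases, the enzymes that load tRNA with amino acids, 10 of 16 rose and none fell (11 and 0 adjusted over the list alone, camera adjusted p = 9.41e-14), including WARS1 at 0.69, SARS1 at 0.63, GARS1 at 0.62 and CARS1, the cysteine enzyme, at 0.57. The ferroptosis-related list had 6 of 19 higher (6 and 0 adjusted over the list alone, camera adjusted p = 5.24e-04), led by CHAC1, SLC7A11 and HMOX1, the haem-degrading enzyme, at 0.74. CHAC1 and SLC7A11 also stand in the ATF4 list, and without genes shared between lists the ferroptosis call was lost (adjusted p = 0.163). Immediate early genes had 8 of 27 higher (14 and 0 adjusted over the list alone, camera adjusted p = 1.01e-09), with ATF3, a stress transcription factor, at 0.82, PHLDA1 at 0.53 and CCN2, a matricellular protein, at 0.46. Among NF-kB targets, 4 of 26 rose (4 and 0 adjusted over the list alone, camera adjusted p = 6.58e-04), among them ICAM1, a cell adhesion molecule, at 0.54. That call was lost with an estimated correlation (adjusted p = 0.556), and without probe sets ending in _x_at or _s_at (adjusted p = 0.111).

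Heat shock genes fell in Vec cells, 9 of 14 with none higher (12 and 0 adjusted over the list alone for falls and rises, camera adjusted p = 1.60e-14). BAG3, a co-chaperone of HSP70, changed by -0.46, DNAJB1, another co-chaperone, by -0.43, and HSPA4L by -0.37. DNA replication genes had 5 of 23 lower and none higher (10 and 0 adjusted over the list alone for falls and rises, camera adjusted p = 6.53e-08), including GINS1, a subunit of the replicative helicase, at -0.34. Mitosis genes had 2 of 24 lower (2 adjusted over the list alone, camera adjusted p = 0.00108), and this call was lost with an estimated correlation (adjusted p = 0.237). The other 6 of these 8 list calls held with an estimated correlation, at adjusted p-values of 0.0395 or less.

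No call was made in Vec cells for the other 16 lists (camera adjusted p between 0.131 and 0.912). In the NRF2 and glutathione list 3 of 28 rose (3 adjusted over the list alone), including SLC7A11, HMOX1 and TXNRD1, a thioredoxin reductase, at 0.30. Of 41 HIF targets, 5 rose and 2 fell (6 and 2 adjusted over the list alone). The risers DDIT4, STC2, a secreted glycoprotein, at 0.81, and VLDLR, a lipoprotein receptor, at 0.43 also stand in the ATF4 list. Of 17 p53 targets 3 rose (3 higher and 1 lower adjusted over the list alone), with GADD45A, a growth arrest gene, at 0.51. The necroptosis and death receptor list had 2 higher and 1 lower of 16 (2 and 1 adjusted over the list alone), the faller being TNFSF10, the death ligand TRAIL, at -0.31. RIPK1, RIPK3 and MLKL are not among these 16 measured genes. Endoplasmic reticulum chaperones had 1 higher and 2 lower of 18, with XBP1, a transcription factor of the unfolded protein response, at 0.84, and interferon response genes 1 higher and 1 lower of 25. Glycolysis, sterol synthesis, extracellular matrix, epithelial junctions, metallothioneins, ribosomal proteins, oxidative phosphorylation and the markers of tubule, blood and endothelium had no called member. Adjusted over the list alone, chaperones had 1 higher and 3 lower, interferon genes 2 and 2, sterol synthesis 1 and 2, epithelial junctions 2 and 1, tubule markers 1 and 0, and the others in that group 0. Of the remaining question genes, VEGFA, an angiogenic growth factor, gave 0.27 ± 0.10 (limma adjusted p = 0.179), CCND1, cyclin D1, -0.13 (0.463), SLC2A1, a glucose transporter, 0.07 (0.610) and TNF, the cytokine that can trigger necroptosis, -0.03 with a 95% interval from -0.17 to 0.11. TNF is dim, with a mean at or under 6.47, so in each comparison its values cannot show that the transcript was unchanged. With the mean of its probe sets VEGFA was called, at 0.271 (limma adjusted p = 0.0143), and without Vec control replicate 1 VEGFA gave 0.148 (0.464) and CCND1 -0.219 (0.159). The HIF list was called with the mean of a gene's probe sets (camera adjusted p = 0.0473), with each probe set on its own (0.0344), with the lower-quartile covariate (0.0372) and without Vec control replicate 2 (0.0145) or Vec deprived replicate 1 (0.0450). Over the camera alternatives its adjusted p ran from 0.0145 to 0.900. Targets of p53 were called without Vec deprived replicate 3 (0.0371), and sterol synthesis with each probe set on its own (0.0439).

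In VHL cells, CHAC1 was again the gene that rose most on deprivation, 5.76-fold (log2 2.52 ± 0.10, limma adjusted p = 3.38e-09, n = 3 per group). INHBE rose by 2.51 ± 0.07, CTH by 2.38 ± 0.09, DDIT4 by 2.26 ± 0.05 and SLC7A11 by 1.59 ± 0.08. CXCL8, the chemokine interleukin 8, rose by 2.16 ± 0.21 (limma adjusted p = 3.27e-05). RGS2, a regulator of G-protein signalling, fell by 1.26 ± 0.12, and 10 of 14 heat shock genes (camera adjusted p = 3.68e-12) and 10 of 23 DNA replication genes (4.28e-07) fell.

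A total of 1392 genes were called in VHL cells, 737 higher and 655 lower, or 11.6%, with a median size of 0.27. With each array centred on its median, the split of calls turned to 550 higher and 873 lower. Changes of at least 1.5-fold numbered 74 higher and 19 lower. PCK2 rose 4.01-fold, and ATF3 by 1.58 on the log2 scale. Other large falls were RHOB at -0.84, CHORDC1 at -0.83, CCNE2, a cyclin of the entry into S phase, at -0.76, CAMTA1 at -0.72, DNAJB1 at -0.64 and B4GALT6, a galactosyltransferase of glycolipid synthesis, at -0.64. SEC24D, a coat protein of vesicles leaving the endoplasmic reticulum, changed by -0.65, but was not called without VHL control replicate 1 (adjusted p = 0.139) or 2 (0.0742) or without VHL deprived replicate 1 (0.113), and gave -0.244 with the mean of its probe sets (0.128). Without those same arrays in turn, called genes numbered 764, 849 and 822, and without probe sets ending in _x_at or _s_at 771.

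Of the ATF4 list, 28 of 36 rose and 1 fell in VHL cells (28 and 1 adjusted over the list alone, median 0.84, camera adjusted p = 9.26e-37), including ASNS at 1.55 and STC2 at 1.39. Of immediate early genes 16 of 27 rose (18 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.12e-11), with KLF4 at 1.56, CCN2 at 0.98 and IER3 at 0.58. NF-kB targets had 11 of 26 higher (12 and 0 adjusted over the list alone, camera adjusted p = 1.52e-07), among them IL6, an inflammatory cytokine, at 1.07 and TNFAIP3, a feedback inhibitor of NF-kB, at 0.98. With an estimated correlation the NF-kB call was lost (adjusted p = 0.319). Aminoacyl-tRNA synthetases had 9 of 16 higher (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 5.44e-08), with CARS1 and WARS1 at 0.75, SARS1 at 0.66 and GARS1 at 0.65, and the call was lost with an estimated correlation (adjusted p = 0.0602). Of p53 targets 6 of 17 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 8.31e-05), among them GADD45A, which also stands in the ATF4 list, DDB2, a DNA repair protein, at 0.33, and ZMAT3, an RNA-binding protein, at -0.47. Ferroptosis-related genes had 6 higher and 1 lower of 19 (7 and 3 adjusted over the list alone, camera adjusted p = 0.0122), including PTGS2, the inducible cyclooxygenase, at 0.95 and TFRC, the transferrin receptor, at 0.57. This call was lost with an estimated correlation (adjusted p = 0.0568) and without genes shared between lists (adjusted p = 0.457).

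Heat shock genes had 10 of 14 lower in VHL cells and none higher (10 and 0 adjusted over the list alone for falls and rises, camera adjusted p = 3.68e-12), with DNAJA1, a co-chaperone, at -0.59 and BAG3 at -0.38. DNA replication had 10 of 23 lower and 1 higher (14 and 1 adjusted over the list alone, camera adjusted p = 4.28e-07). MCM10, a replication initiation factor, changed by -0.60, GINS1 by -0.47 and PCNA, the sliding clamp, by -0.37. Sterol synthesis had 3 of 16 lower (4 adjusted over the list alone, camera adjusted p = 0.0127), led by HMGCS1, an early enzyme of the pathway, at -0.39. With the mean of its probe sets HMGCS1 gave -0.168 and was not called (limma adjusted p = 0.137). The sterol call was lost with an estimated correlation (adjusted p = 0.156), with the mean of a gene's probe sets (0.0792), with the lower-quartile covariate (0.0517) and without VHL deprived replicate 1 (0.0695). The ATF4, immediate early, p53, DNA replication and heat shock calls held with an estimated correlation.

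The other 15 lists were not called in VHL cells (camera adjusted p between 0.129 and 0.951). Of 41 HIF targets 11 rose and 2 fell (12 and 3 adjusted over the list alone). This list was called with quantile normalization (camera adjusted p = 0.0459), with the mean of a gene's probe sets (0.0418), with each probe set on its own (0.0174), with the lower-quartile covariate (0.0236) and without VHL control replicate 1 (0.0479). Over the camera alternatives its adjusted p ran from 0.0174 to 0.931. VEGFA rose by 0.75 ± 0.10 (limma adjusted p = 3.77e-04), EDN1, the vasoconstrictor endothelin 1, by 0.60, and JMJD6, an iron-dependent dioxygenase, changed by -0.48. SLC2A1 rose by 0.28 ± 0.06 (limma adjusted p = 0.00882), but gave 0.097 with the mean of its probe sets (0.259) and -0.084 without probe sets ending in _x_at or _s_at. The NRF2 and glutathione list had 5 higher and 2 lower of 28 (6 and 2 adjusted over the list alone), with TXNRD1 at 0.52, MAFG, a partner of NRF2, at 0.36 and UGDH, which makes UDP-glucuronate, at -0.52. Interferon response genes had 5 higher and 3 lower of 25, including IRF7, a transcription factor of the response, at 0.56 and IFIT1 at -0.54. Mitosis had 4 higher and 3 lower of 24, with CENPA, the centromeric histone, at 0.32. Necroptosis and death receptor genes had 1 higher and 2 lower of 16, with TNFSF10 at -0.63, and TNF gave 0.06 with a 95% interval from -0.08 to 0.21. Endoplasmic reticulum chaperones had 2 higher and 1 lower of 18, with XBP1 at 0.62 and HERPUD1, an ER-associated degradation protein, at 0.37. Oxidative phosphorylation had 1 higher and 3 lower of 28, epithelial junctions 3 of 17 higher, with KRT7 at 0.42 (called as a list with each probe set on its own, camera adjusted p = 0.0206), and extracellular matrix 1 of 29 higher. Glycolysis, metallothioneins, ribosomal proteins and the tubule, blood and endothelial markers had no called member. Adjusted over the list alone, mitosis had 4 higher and 4 lower, necroptosis 2 and 2 and epithelial junctions 5 and 0, while the other lists gave equal counts. CCND1 gave -0.18 (limma adjusted p = 0.163).

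**Figure D1:**
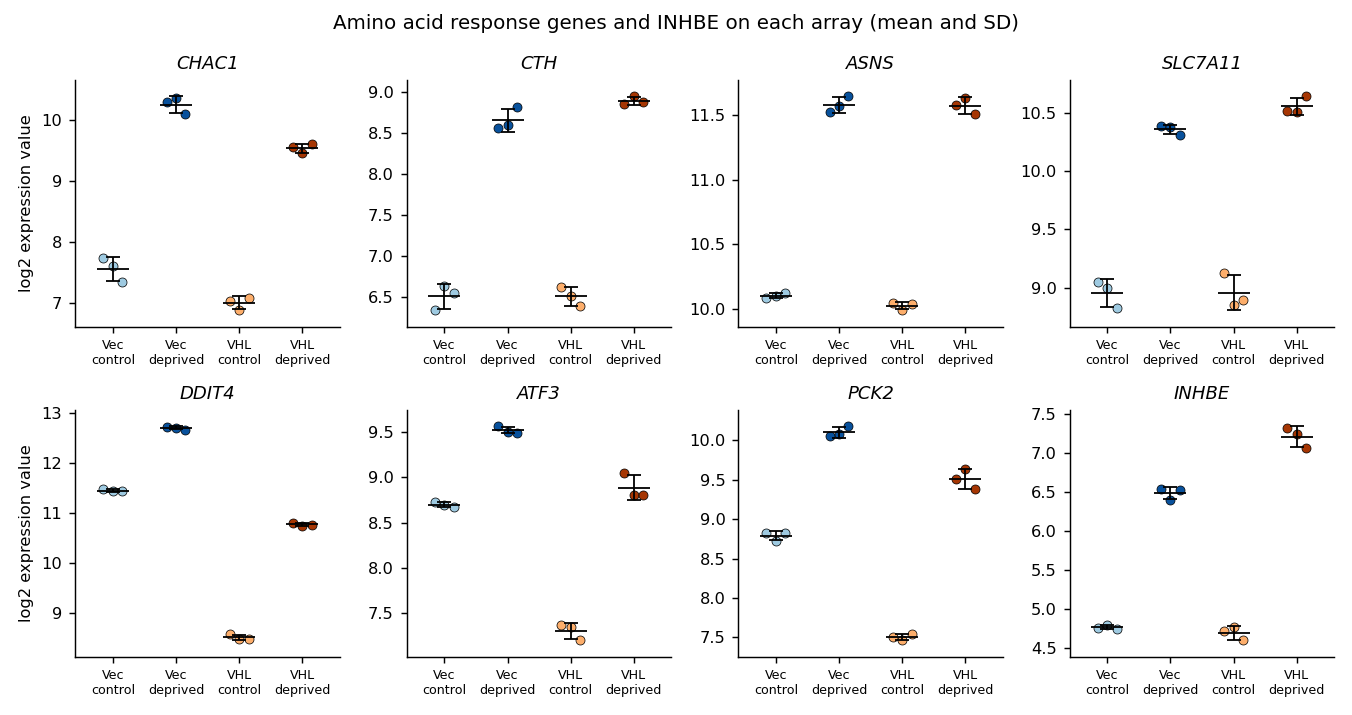
Log2 expression on each array for 8 genes in the 4 groups, with group means and SD (n = 3 arrays per group, y-axis range set for each gene). Each gene was higher in deprived than in control medium in both lines, CHAC1 by 2.68 in Vec and 2.52 in VHL cells and DDIT4 by 1.25 and 2.26.

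The responses of both lines overlapped. Of the 253 genes that rose in Vec cells 190, or 75.1%, also rose in VHL cells, against 15.6 expected if the calls were independent (Fisher's exact test, p = 1.55e-182), and of the 247 that fell 147, or 59.5%, fell in both, against 13.5 expected (Fisher's exact test, p = 2.71e-124). This test treats genes as independent, which they are not, so its p-values overstate the evidence. Both sets of calls also use the same variance estimate for each gene. HOXC6, a homeobox transcription factor, was the single gene called in opposite directions and is named outside the rule, after its values were seen, at -0.29 in Vec and 0.18 in VHL cells. Across all 11963 genes, which are not independent replicates, the log2 responses correlated with a Pearson coefficient r of 0.602 and a Spearman rank coefficient of 0.423. Values had the same sign in both lines for 64.1% of these genes. Across the 1554 genes called in either line, which were selected for a change, r was 0.826 and 91.3% had the same sign. The main axis of their scatter, which is not a regression of VHL on Vec responses, had a slope of 1.51. Of these genes 1392 were called in VHL and 500 in Vec cells, so the slope cannot give the relative size of the responses. Without Vec deprived replicate 1 the shared rises numbered 124 and the shared falls 62, and without Vec deprived replicate 2 they were 124 and 77. Shared falls also lay between 71 and 84 without any 1 of the other 4 Vec arrays, and at 97 without VHL deprived replicate 3.

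**Figure D2:**
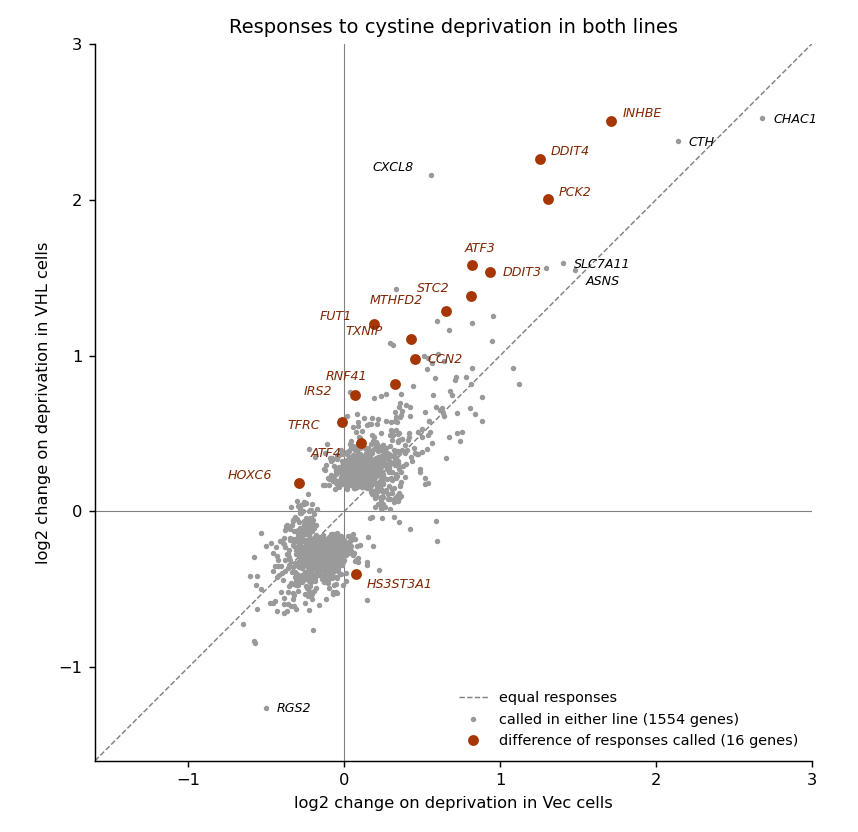
Log2 response to deprivation in VHL cells against that in Vec cells for the 1554 genes called in either line, with the dashed line marking equal responses and the 16 genes whose responses differed marked. The main axis of the scatter, which is not a regression line, had a slope of 1.51. Of the 16 marked genes, 15 lie above the dashed line.

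The difference between the responses was called for 16 of 11963 genes, 15 with a higher value in VHL cells and 1 with a lower value. With a variance trend and robust moderation the split was 32 higher and 13 lower. DDIT4 differed most surely, 2.01-fold (log2 1.01 ± 0.06, limma adjusted p = 1.31e-05, n = 3 per group), after rises of 1.25 in Vec and 2.26 in VHL cells. INHBE differed by 0.79 ± 0.10, ATF3 by 0.76, PCK2 by 0.70, MTHFD2, a mitochondrial enzyme of folate metabolism, by 0.63 and STC2 by 0.57. IRS2, an adaptor of insulin signalling, differed by 0.68 ± 0.06 (limma adjusted p = 1.56e-04), with a rise of 0.74 in VHL cells and a value of 0.07 in Vec cells that was not called (0.443), and TFRC by 0.59, with a rise of 0.57 in VHL cells and -0.02, not called, in Vec cells. TXNIP, which binds thioredoxin, differed by 0.68.

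FUT1, a fucosyltransferase, had the largest difference among the 16 called genes, 1.02 ± 0.15 (limma adjusted p = 0.0142), from a dim level of 5.30 in Vec control cells, and was not called without Vec control replicate 2 (adjusted p = 0.0602) or Vec deprived replicate 1 (0.0536). CCN2 differed by 0.52 and HS3ST3A1, a heparan sulfate sulfotransferase, by -0.48. CCN2 was not called without any 1 of 9 arrays, all but Vec control replicate 1, VHL control replicate 2 and VHL deprived replicate 3 (adjusted p between 0.0591 and 0.116), and HS3ST3A1 without any 1 of 11, all but VHL control replicate 2 (0.0566 to 0.107). Among the 16 genes, 10 rose in both lines and 13 had a lower level in VHL than in Vec control cells, called or not. The control arrays enter this level and the difference of responses with opposite signs. Genes picked for a positive difference therefore lean toward a lower level in VHL control cells. That lean is on the scale of the error, a median of 0.066 over all genes in control medium. It is too small to account for levels lower by -2.98 for IRS2, -2.94 for DDIT4, -1.40 for ATF3, -1.30 for TFRC, -1.29 for PCK2 or -0.75 for STC2. INHBE at -0.07 and RNF41, a ubiquitin ligase, at -0.05 lie within that scale. SLC7A11 and CHAC1 were not called, at 0.19 (95% interval -0.04 to 0.43) and -0.16 (-0.45 to 0.14), nor were VEGFA at 0.49 (limma adjusted p = 0.298), SLC2A1 at 0.21 (0.435), CCND1 at -0.05 (0.911), VHL at -0.19 (0.440) and TNF at 0.09 (-0.11 to 0.30). SLC2A1 gave -0.101 without probe sets ending in _x_at or _s_at and 0.053 with the mean of its probe sets. CXCL8 differed by 1.61 ± 0.30 and was not called (limma adjusted p = 0.0727). It was called without genes at or under a mean of 6.47 (0.0457), with array weights (0.0382) and, at 1.83, without VHL control replicate 1 (0.0160). Over all alternatives its adjusted p ran from 0.0160 to 0.196.

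By group, the ATF4 list had 7 of 36 members with a larger response in VHL cells and none with a smaller one (13 and 0 adjusted over the list alone, median 0.14, camera adjusted p = 5.09e-11), and this call held with an estimated correlation (adjusted p = 0.00136). The mean difference was 0.278 ± 0.022 over the 25 members lower in VHL control cells and 0.074 ± 0.061 over the other 11. This grouping shares control arrays with the difference. Immediate early genes had 2 of 27 (6 higher and 1 lower adjusted over the list alone, median 0.13, camera adjusted p = 0.00129), ATF3 and CCN2, and the call was lost with an estimated correlation (adjusted p = 0.494). NF-kB targets had no called member among 26 (3 and 0 adjusted over the list alone, median 0.10, camera adjusted p = 0.00115). Their call was lost with an estimated correlation (adjusted p = 0.614) and without VHL deprived replicate 1 (adjusted p = 0.118). For p53 targets none of 17 was called (4 and 0 adjusted over the list alone, median 0.07, camera adjusted p = 0.0148), and the list call was lost with an estimated correlation (adjusted p = 0.138) and without probe sets ending in _x_at or _s_at (adjusted p = 0.247). The other 20 lists were not called (camera adjusted p between 0.123 and 0.880). Mitosis was called, higher, with 4 alternatives (0.0112 to 0.0425) and without Vec control replicate 3 (0.0248), Vec deprived replicate 3 (0.0344) or VHL deprived replicate 1 (0.0357). Heat shock was called, lower, with the mean of a gene's probe sets (0.0322) or with each on its own (0.00191). The 20 lists held called members only among HIF targets, DDIT4 and STC2 of 41, and ferroptosis-related genes, TFRC of 19. Adjusted over the list alone, HIF targets had 7 higher and 1 lower, interferon response 4 and 1, mitosis 2 and 0, and each other of the 20 lists at most 1 member.

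VHL cells differed from Vec cells in control medium far more widely than either line changed on deprivation. HIF targets were lower with VHL put back: SLC2A1 was 4.86-fold lower (log2 -2.28 ± 0.06, limma adjusted p = 4.40e-12, n = 3 per group), CCND1 2.84-fold and VEGFA 2.54-fold lower. CA12, a carbonic anhydrase, differed by -3.20, ADM, the peptide hormone adrenomedullin, by -3.56, and EGLN3, a HIF prolyl hydroxylase, by -3.24. KL, the kidney protein klotho, was higher in VHL cells, at a log2 level of 10.21 against 3.88 in Vec cells. SLC7A11 did not differ detectably, at 0.00 ± 0.08 with a 95% interval from -0.16 to 0.17.

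A total of 5520 of 11963 genes, or 46.1%, were called, 2763 higher and 2757 lower in VHL cells, and 1508 of them differed at least 1.5-fold, 738 higher and 770 lower. The level of KL in Vec cells lies near the lower end of the arrays, so background limits its difference and no fold is given. VAMP8, a membrane fusion protein, was higher by 5.36, ANXA3, an annexin, by 5.20, CCND2, cyclin D2, by 4.99, NLGN1, a synaptic adhesion protein, by 4.63, RGS5, a regulator of G-protein signalling, by 4.43, ALDH2, the mitochondrial aldehyde dehydrogenase, by 4.24 and FUT9, a fucosyltransferase, by 4.06. The most strongly lower genes were COXFA4L2, a mitochondrial protein induced by hypoxia, at -5.69 ± 0.12, STC1, a secreted glycoprotein, at -5.16, OLFML3 at -4.82, DEPP1 at -4.55, COL13A1, a membrane collagen, at -4.04, AUTS2 at -3.97, GNAL, a G-protein subunit, at -3.90 and INHBA, an activin subunit, at -3.87. CHAC1 was lower by -0.55 (limma adjusted p = 2.93e-04) and TNF gave -0.07 (limma adjusted p = 0.444). Without probe sets ending in _x_at or _s_at 3427 genes were called.

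Of the 41 HIF targets, 34 were lower and 1 higher in VHL control cells (35 and 1 adjusted over the list alone, median -1.34, camera adjusted p = 7.72e-20). Glycolysis genes had 13 of 17 lower and 2 higher (14 and 2 adjusted over the list alone, camera adjusted p = 4.28e-05), with ENO2, an enolase, at -2.68, ALDOC, an aldolase, at -1.82, and the hexokinases HK2 at -1.48 and HK1 at -1.40. Sterol synthesis had 12 of 16 lower and 1 higher (12 and 1 adjusted over the list alone, camera adjusted p = 1.37e-04), including ACAT2 at -1.15, DHCR7, which catalyses the last step to cholesterol, at -1.14 and LSS, lanosterol synthase, at -0.90. The ATF4 list was also lower, 19 of 36 against 7 higher (19 and 7 adjusted over the list alone, camera adjusted p = 0.00501), with DDIT4 at -2.94, ATF3 at -1.40, PCK2 at -1.29 and ATF4 itself at -0.72. Interferon response genes were higher, 14 of 25 against 2 lower (14 and 2 adjusted over the list alone, camera adjusted p = 0.00263), with IFIT1 at 2.64, IFI44L at 1.63 and IRF9, a transcription factor of interferon signalling, at 0.96. These 5 calls held with an estimated correlation, at adjusted p-values of 0.0464 or less.

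Another 5 list calls in control medium were lost with an estimated correlation. Immediate early genes had 20 of 27 lower and 2 higher (21 and 2 adjusted over the list alone, camera adjusted p = 2.29e-06, estimated-correlation adjusted p = 0.101), with DUSP1, a MAP kinase phosphatase, at -1.74, JUN at -1.42 and SPRY2 at -1.38. NF-kB targets had 17 of 26 lower and 3 higher (17 and 3 adjusted over the list alone, camera adjusted p = 1.37e-04, estimated-correlation adjusted p = 0.518), with CXCL8 at -3.39, TNIP1 at -1.38 and VCAM1, an adhesion molecule, at -0.95. Mitosis genes had 16 of 24 higher and 4 lower (16 and 4 adjusted over the list alone, camera adjusted p = 8.29e-04, estimated-correlation adjusted p = 0.187), with DLGAP5, a spindle protein, at 1.01 and the cyclins CCNB1 at 0.81 and CCNB2 at 0.70. Oxidative phosphorylation had 17 of 28 higher and 6 lower (17 and 7 adjusted over the list alone, camera adjusted p = 0.00542, estimated-correlation adjusted p = 0.208), with UQCRC2, a complex III subunit, at 1.19, SDHC, a complex II subunit, at 0.82 and UQCRB, another complex III subunit, at -0.86. Without probe sets ending in _x_at or _s_at that call was also lost (adjusted p = 0.240). Ferroptosis-related genes had 8 of 19 lower and 2 higher (8 and 2 adjusted over the list alone, camera adjusted p = 0.0410, estimated-correlation adjusted p = 0.110), with HMOX1 at -1.53, TFRC at -1.30 and SAT1, a polyamine acetyltransferase, at -1.28. The call was lost without Vec control replicate 2 (adjusted p = 0.0531) or VHL control replicate 3 (0.0548). It was also lost without genes at or under a mean of 6.47 (0.154), with the mean of a gene's probe sets (0.172) and with only the groups compared (0.0605).

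**Figure D3:**
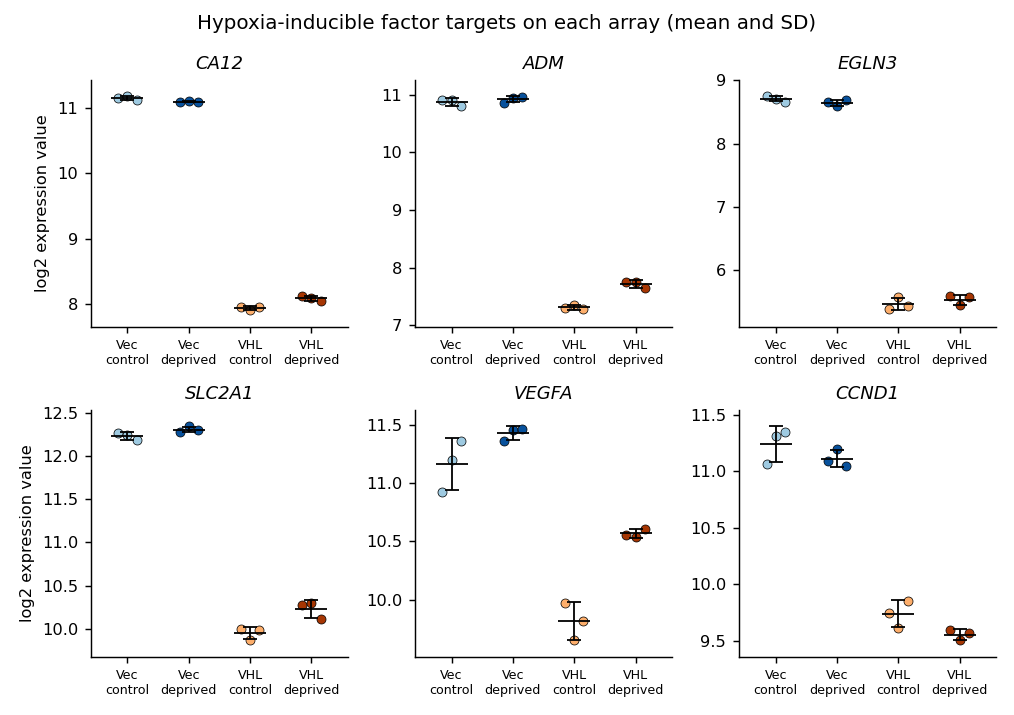
Log2 expression on each array for 6 HIF target genes in the 4 groups, with group means and SD (n = 3 arrays per group, y-axis range set for each gene). Each gene was lower in VHL than in Vec cells in both media, ADM by a log2 difference of -3.56 in control and -3.20 in deprived medium.

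The other 14 lists were not called in control medium (camera adjusted p between 0.0857 and 0.980), though many of their members were, in both directions. The NRF2 and glutathione list had 13 higher and 5 lower of 28, with GSR, glutathione reductase, at 1.21 and NQO1, a quinone reductase, at 1.09. It was called without genes shared between lists (camera adjusted p = 0.0326) and with each probe set on its own (0.00778). Extracellular matrix genes had 8 higher and 10 lower of 29, with COL5A1, a fibrillar collagen chain, at -3.11, MMP1, a collagenase, at 2.53 and FN1, fibronectin, at 1.48. Epithelial junctions had 5 higher and 5 lower of 17, with KRT19 at -1.36 and CDH16, a kidney cadherin, at 1.09. DNA replication had 8 higher and 10 lower of 23, endoplasmic reticulum chaperones 7 and 6 of 18, p53 targets 4 and 7 of 17, and aminoacyl-tRNA synthetases 4 and 5 of 16. Heat shock had 5 higher and 3 lower of 14, with CRYAB, a small heat shock protein, at 3.16, and necroptosis and death receptor genes 3 and 6 of 16, with TRADD, an adaptor of the TNF receptor, at 0.42 and FADD, an adaptor of death receptors, at -0.35 (called as a list, lower, with each probe set on its own, camera adjusted p = 0.0263). Ribosomal proteins had 6 lower of 24, metallothioneins 1 higher and 1 lower of 9, and tubule markers 2 higher of 9, with MME, the protease neprilysin, at 1.04. Blood cell markers had 1 lower of 10, CSF1R, a cytokine receptor, at -0.73, and endothelial markers had no called member. Adjusted over the list alone, heat shock had 5 higher and 4 lower and ribosomal proteins 5 lower, and the other 12 lists gave equal counts.

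In deprived medium the lines differed much as in control medium. SLC2A1 was 4.22-fold lower in VHL cells (log2 -2.08 ± 0.06, limma adjusted p = 1.13e-11, n = 3 per group), ADM differed by -3.20 and EGLN3 by -3.11, while VEGFA differed by -0.86 and CCND1 by -1.56. DDIT4, after its larger rise in VHL cells, remained lower there by a log2 difference of -1.93. KL was higher, at 9.60 against 3.90 in Vec cells, again near the lower end of the arrays, COXFA4L2 was 45.3-fold lower, and CHAC1 was lower at -0.71. SLC7A11 gave 0.20 ± 0.08 (limma adjusted p = 0.0522) and TNF 0.03 (limma adjusted p = 0.792). SLC7A11 was called with 6 of the alternatives (0.0186 to 0.0408).

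A total of 5650 genes were called, or 47.2%, 2897 higher and 2753 lower, and 1491 differed at least 1.5-fold, 752 higher and 739 lower. With KL left out for its dim level in Vec cells, the largest positive differences were ANXA3 at 5.32, VAMP8 at 5.29, CCND2 at 4.84, NLGN1 at 4.45, SLC34A2, a phosphate transporter, at 4.36, ALDH2 at 4.24 and RGS5 at 4.21. The largest negative ones besides COXFA4L2 were STC1 at -4.89, OLFML3 at -4.77, DEPP1 at -4.36, COL13A1 at -3.94, SPINK1, a trypsin inhibitor, at -3.86, AUTS2 at -3.75 and GNAL at -3.68. Without probe sets ending in _x_at or _s_at 3505 genes were called.

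HIF targets had 35 of 41 lower and 1 higher in deprived VHL cells (35 and 1 adjusted over the list alone, median -1.36, camera adjusted p = 1.25e-20), glycolysis 12 of 17 lower and 2 higher (13 and 2 adjusted over the list alone, camera adjusted p = 2.71e-05), with ENO2 at -2.68, and sterol synthesis 13 of 16 lower and 1 higher (14 and 1 adjusted over the list alone, camera adjusted p = 2.71e-05), with DHCR7 at -1.19. Interferon response genes had 14 of 25 higher and 2 lower (16 and 2 adjusted over the list alone, camera adjusted p = 2.66e-04), with IFIT1 at 2.34 and IRF9 at 1.17. These 4 calls held with an estimated correlation, at adjusted p-values of 0.0402 or less. The next 5 did not. Mitosis had 19 of 24 higher and 4 lower (19 and 4 adjusted over the list alone, camera adjusted p = 4.50e-05, estimated-correlation adjusted p = 0.143), and immediate early genes 19 of 27 lower and 3 higher (19 and 3 adjusted over the list alone, camera adjusted p = 4.50e-05, estimated-correlation adjusted p = 0.144), with DUSP5 at -2.37. NF-kB targets had 17 of 26 lower and 4 higher (17 and 4 adjusted over the list alone, camera adjusted p = 0.00158, estimated-correlation adjusted p = 0.627), with BCL2A1, an apoptosis inhibitor, at -1.78. Oxidative phosphorylation had 17 of 28 higher and 4 lower (17 and 5 adjusted over the list alone, camera adjusted p = 0.0143, estimated-correlation adjusted p = 0.298, and 0.249 without probe sets ending in _x_at or _s_at), and ferroptosis-related genes 10 of 19 lower and 2 higher (11 and 4 adjusted over the list alone, camera adjusted p = 0.0234, estimated-correlation adjusted p = 0.104, 0.157 without genes at or under a mean of 6.47 and 0.106 with the mean of a gene's probe sets), with HMOX1 at -1.81.

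The ATF4 list was not called in deprived medium, with 10 higher and 14 lower of 36 (11 and 15 adjusted over the list alone, camera adjusted p = 0.420). CBS, which makes cystathionine, was higher at 1.33, NUPR1, a stress-induced regulator, at 0.55, and SHMT2, a mitochondrial serine hydroxymethyltransferase, lower at -0.69. The other 14 lists were not called either (camera adjusted p between 0.0782 and 0.990). The NRF2 and glutathione list had 14 higher and 5 lower of 28, with GSR at 1.27, and necroptosis and death receptor genes 3 higher and 6 lower of 16, with TRADD at 0.53 and TNFSF10 at -0.54. Both were called with each probe set on its own (camera adjusted p = 0.00873 and 0.00706), and the former without genes shared between lists (0.0378). DNA replication had 7 higher and 11 lower of 23, aminoacyl-tRNA synthetases 4 and 7 of 16, endoplasmic reticulum chaperones 7 and 6 of 18, p53 targets 6 and 3 of 17, extracellular matrix 8 and 9 of 29, epithelial junctions 5 and 6 of 17 and heat shock 4 and 3 of 14. Ribosomal proteins had 1 higher and 7 lower of 24, metallothioneins 2 and 2 of 9, tubule markers 2 and 2 of 9, blood cell markers 1 and 1 of 10, and endothelial markers no called member. Adjusted over the list alone, NRF2 and glutathione had 16 higher and 6 lower, DNA replication 7 and 12, extracellular matrix 10 and 9 and heat shock 4 and 5, and the other 10 lists gave equal counts.

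**Figure D4:**
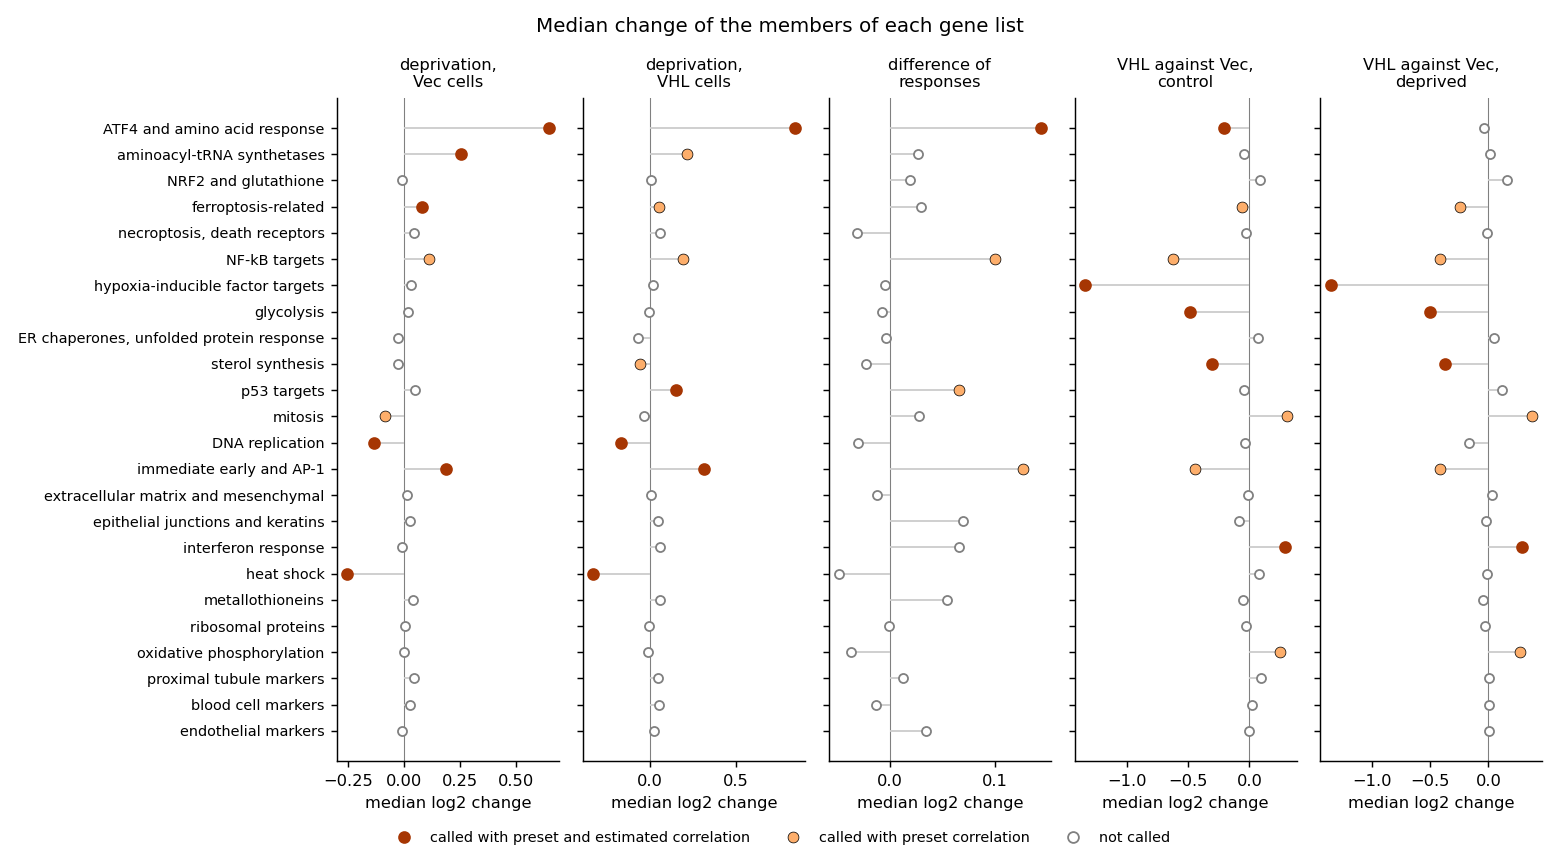
Median log2 change of each of the 24 gene lists in the 5 comparisons, with dark points for lists called with the preset and the estimated correlation, light points for the preset only and open points for lists not called. The x-axis scale differs between panels, and HIF targets lie at -1.34 and -1.36 in the comparisons of VHL with Vec cells.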

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

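In this part, the test of bright probe sets and the covariate on each array's lower quartile were chosen only after the result was seen. The other tests were chosen before.

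The response to deprivation differed between the lines, by a test of the difference itself, for 16 genes. On the log2 scale, as VHL minus Vec, the differences were 1.02 for FUT1, 1.01 for DDIT4, 0.79 for INHBE, 0.76 for ATF3, 0.70 for PCK2, 0.68 for TXNIP, 0.68 for IRS2, 0.63 for MTHFD2, 0.60 for DDIT3, a stress transcription factor that promotes cell death, 0.59 for TFRC, 0.57 for STC2, 0.52 for CCN2, 0.49 for RNF41, a ubiquitin ligase, 0.47 for HOXC6, 0.33 for ATF4 and -0.48 for HS3ST3A1. DDIT3, RNF41, HOXC6 and ATF4 fall outside the naming rule and were named after their values were seen. By the preset-correlation test of the lists, median differences of 0.14 for the ATF4 list, 0.13 for immediate early genes, 0.10 for NF-kB targets and 0.07 for p53 targets were called, of which the ATF4 list alone held with an estimated correlation. The adjusted p-values of the others were then 0.494 for immediate early genes, 0.614 for NF-kB targets and 0.138 for p53 targets. The NF-kB call was also lost without VHL deprived replicate 1 (adjusted p = 0.118). Of 100 splits of the 12 arrays, the real one and others drawn at random, only the real one gave as many genes. With line and medium effects removed first, it gave 72 genes, against 1 in the highest other. This version is not the test that called 16 genes, and in the other splits the real difference adds to the spread. It therefore cannot exclude chance, and with 100 splits the share cannot go under 1 in 100.

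Genes of the ATF4 list rose more in VHL cells, by a mean of 0.215 ± 0.018 over 36 members. A single array is argued against as the cause, since the mean was 0.206 or more whichever of the 12 arrays was left out. Compressed signal at the higher starting levels of Vec cells stays open: the mean was 0.278 ± 0.022 over the 25 members lower in VHL control cells, but 0.074 ± 0.061 over the other 11, a grouping that shares control arrays with the difference. Saturation of bright probe sets also stays open, as the 9 members under the upper quartile of 9.17 in deprived Vec cells had a mean of 0.034 ± 0.047. In both lines those 9 members rose less than the whole list, by means of 0.342 in Vec and 0.377 in VHL cells. The whole list rose by 0.663 and 0.878. Their small difference is therefore not in itself a sign of saturation. A larger response with VHL put back may be biological, but cannot be told apart from these limits of the scale with so few members below them.

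More genes were called on deprivation in VHL than in Vec cells, 1392 against 500, a ratio of 2.78, which does not by itself show that the responses differ. Differences in the arrays' distributions are argued against as the whole cause, since with the lower quartile as a covariate the ratio was 1.77. A single VHL array is argued against too, as the ratio was 1.63 or more whichever VHL array was left out. The lowest ratios, 1.63 and 1.64, came without VHL deprived replicate 1 and VHL control replicate 1. Leaving out 1 Vec array gave 4.12 to 5.23, but with fewer Vec arrays the Vec count fell to between 253 and 303. Those refits therefore say little about a single Vec array. More noise in VHL arrays, which could raise their count in a fit that pools the variance of all 12 arrays, is argued against as the whole cause, since fits of each line alone, with its own variance, gave 835 genes in VHL and 311 in Vec cells, a ratio of 2.68. A broader or larger response in VHL cells may be biological, as a hypothesis, while compressed signal in Vec cells was not tested for this count.

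Nearly as many genes differed between the lines as did not, and in control medium 38 of 222 runs of 50 neighbouring genes had a shifted median, 13 higher and 25 lower, against at most 2 in 1000 shuffled gene orders. Differences in chromosome copies between the derived lines may contribute. Shuffling also separates neighbouring genes that are regulated together, so the runs cannot tell these apart. The run from MPHOSPH8 to KL had a median of 0.40, with 28 genes higher and 2 lower, the run from STARD13 to ITM2B also 0.40 and that from GRK5 to MTG1 -0.36. Most calls lay outside the shifted runs, where 43.8% of genes were called, against 58.4% inside. Copy differences shorter than a run, or split between neighbouring runs, need not shift a median. These shares therefore do not bound what such differences contribute. In deprived medium 40 runs were shifted, and for the responses to deprivation 1 run in Vec and 3 in VHL cells, against at most 3 and 2 in the shuffles.

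For the other counts the splits of 6 arrays into 3 and 3 are too few for a share under 0.05, with 1 of 10 splits, the real one, giving as many genes in each case. The real and highest other counts were 500 and 1 for deprivation in Vec cells, 1392 and 0 in VHL cells, 5520 and 0 for VHL against Vec cells in control medium and 5650 and 0 in deprived medium. Each other split mixes the real groups, so a real difference adds to its spread. The low counts of the other splits therefore cannot exclude chance.

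Signal was also found in probe sets that the comparisons do not use. Among probe sets naming several genes, 29 were called on deprivation in Vec cells, 92 in VHL cells and 5 for the difference of responses, and among those naming no gene 25 were called in Vec and 94 in VHL cells.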

How the results depend on the processing

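The lower-quartile covariate was chosen after the data were seen, and the other alternatives before. Counts within 1.5 times the main value are not listed, and where no cause is named the cause was not tested. With a 1.5-fold minimum, called genes numbered 47 for deprivation in Vec cells, 93 in VHL cells, 10 for the difference, 1508 and 1491 for VHL against Vec cells in control and deprived medium, and 37 shared rises and 1 shared fall. At an adjusted p under 0.01 they numbered 176, 555 and 8, with 102 shared rises and 34 shared falls. Both are stricter by construction. Without probe sets ending in _x_at or _s_at, which leaves fewer genes to test, they were 233, 771, 3427 and 3505 (Vec, VHL, control, deprived), with 103 and 55 shared. A fit of the compared groups alone, with fewer samples, gave 311 and 835, with 65 shared falls. Shared falls rose to 233 without genes at or under a mean of 6.47, and to 233 with a variance trend and robust moderation, which gave 45 genes for the difference. The covariate gave 893 genes for deprivation in VHL cells. Replicate number as a block gave 434, 1326 and 16 genes for the responses and their difference. With it the difference passed the test for CXCL8 (adjusted p = 0.0435), while CAVIN2 (0.0536), CYLD (0.0559) and PLK3 (0.0672) on Vec deprivation, SEC24D (0.0582), CYLD (0.0572), NDUFV1 (0.0523) and SDHD (0.0605) on VHL deprivation, HS3ST3A1 and CCN2 (0.0764) for the difference and the ferroptosis list in control medium (0.0518) did not.

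Leaving out 1 array in turn gave 253 to 303 genes for Vec deprivation, 764 to 1302 for VHL, 11 to 16 for the difference, 5085 to 5274 and 5226 to 5416 between the lines, 124 to 166 shared rises, 62 to 111 shared falls, r across genes of 0.518 to 0.629, and 0.11 to 0.16 and -0.11 to -0.011 for the VHL transcript in control and deprived medium. The lowest VHL count, 764, came without VHL control replicate 1. The VHL transcript in control medium passed the test with median centring (0.17), the mean of a gene's probe sets (0.14) and the replicate block (0.14).

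With an estimated correlation the called lists numbered 5 for VHL deprivation, 1 for the difference, 5 for control and 4 for deprived medium. With fry, which tests a list without comparing it with other genes, they numbered 2 for the difference and 18 and 19 between the lines. List results across alternatives were unaltered in call 2405 times, went 54 times to a call and 41 times to its loss, with 0 reversed. For lists and named genes, a reversal was counted only where the main or the alternative setting made a call. Changes of direction between uncalled results are therefore not among the reversals. Named genes went 7242 times unaltered, 57 times to a call, 239 times to its loss and 31 times to a value moved beyond its spread. The 5 that reversed were BUB1 on VHL deprivation at 0.035 with the mean of its probe sets and, without probe sets ending in _x_at or _s_at, SLC2A1 on VHL deprivation at -0.084, IFI44 and CFLAR between the lines in control medium at -0.033 and 0.037, and GDF15 in deprived medium at -0.041. Scalings moved the median of all genes by under 0.1. Signal over background limits folds of dim genes.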

Other observations

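The genes in this part were chosen after their values were seen, and no test was added for them. In control medium SLC3A1, the partner subunit of a cystine transporter, was higher in VHL than in Vec cells by 2.73 ± 0.09 on the log2 scale, while its transport subunit SLC7A9 gave 0.02 (limma adjusted p = 0.892). SLC1A1, a glutamate transporter that also takes up cysteine, was lower, at -3.46 ± 0.08. In deprived medium the differences were 2.85 for SLC3A1 and -3.39 for SLC1A1, and neither gene was called on deprivation in either line. MGST2, a microsomal glutathione transferase, was higher by 1.99 ± 0.06 in control medium and GSTP1, a cytosolic one, by 0.72, along with the sulfide-oxidizing enzymes SQOR at 0.58 and ETHE1 at 0.65. GPX4, which reduces lipid peroxides, gave 0.02 (limma adjusted p = 0.784), and GCLC, which makes the precursor of glutathione, 0.00. CBS rose on deprivation by 0.77 in VHL cells (limma adjusted p = 0.00170) and gave 0.03 in Vec cells (0.933), and the difference of 0.73 was not called (0.195).

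In control medium 5 genes for secreted proteins, picked by their values, were each lower in VHL than in Vec cells. INHBA differed by -3.87 ± 0.14, IL11, a cytokine of the IL6 family, by -3.20 ± 0.17, IL6 by -2.12 ± 0.16, LIF, of the same family, by -1.07 ± 0.08 and PTX3, a pattern-recognition protein, by -0.65 ± 0.15. On deprivation all 5 rose in VHL cells, INHBA by 1.43, PTX3 by 1.08, IL6 by 1.07, IL11 by 0.57 and LIF by 0.41. In Vec cells none of the 5 was called, with 0.33 for INHBA, 0.29 for PTX3, 0.31 for IL6, 0.30 for IL11 and 0.10 for LIF. The difference of responses was not called either, at 1.10 for INHBA (limma adjusted p = 0.0727), 0.79 for PTX3 (0.275), 0.76 for IL6 (0.302), 0.28 for IL11 (0.731) and 0.31 for LIF (0.390).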
